A study of Homo sapiens with 9 samples.

How the data were processed

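RNA-seq libraries of human T cells were compared in 3 groups of 3: Tact DMSO, Tex DMSO and Tex mezigdomide. Per the labels' protocols, cells were fixed and frozen and total RNA was sequenced by a company. Groups and replicate numbers were taken from the sample titles. The labels give the source as a cell line without naming one and the cell type as T-cell. They give no dose, treatment time or donor, so p-values measure only the spread between these libraries.

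The deposited files give 1 table per library with an Ensembl gene ID and an estimated count (expected count) per gene. From 87.5 to 88.9% of the values were whole numbers and the rest fractional. The submitters' processing notes name the genome build GRCh38, and also MACS3 3.0.1, a peak caller that makes no gene counts. The aligner, the quantifier and the gene annotation are not given in the sources used here. Each table had 58394 entries, 92 of them ERCC spike-ins, and library totals ran from 71549016 to 140410969. The spike-ins were left out of the totals used for CPM and of all tests, except under spike-in scaling. Symbols were found for 57532 of 58302 gene IDs in a table of gene names, and for 58039 (99.5%) with GENCODE 29 on GRCh38, which also gave positions. The 519 entries of chromosome Y, XIST and TSIX were left out, which kept 57783.

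Estimated counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (17815 tested), libraries were scaled by TMM, and a quasi-likelihood model was fitted over all 9 libraries with 1 coefficient per group and no covariate. Each of 3 comparisons was tested with Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. CPM use the library totals with TMM factors, which ran from 0.921 to 1.056. With 3 libraries against 3, a permutation test of 1 gene could not give a p under 0.1, so no such test was used.

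Gene lists, 39 in all, were tested in each comparison (117 tests, adjusted together) with camera in limma 3.58.1, with a preset correlation between genes of 0.01. The tests were repeated with a correlation estimated from the data and with fry, which asks whether a list moves one way and makes no comparison with other genes. The lists covered the Ikaros family, the cereblon pathway, inhibitory receptors, exhaustion transcription factors, naive and memory, cytotoxic, cytokine, chemokine, receptor, homing, signalling, costimulation, AP-1, NF-kB, NFAT, interferon, cell cycle, histone, p53, metabolic, stress, mitochondrial and helper T cell genes. They also covered markers of gamma delta T cells, NK cells, B cells, plasma cells, monocytes, dendritic cells, red cells and platelets, and stromal cells. The groups, design, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined.

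IKZF1, IKZF3 and CRBN were always named. In each comparison the 8 highest and 8 lowest log2 fold changes were named among called genes with a mean log2 CPM of at least 2 and library values that did not overlap. Genes without an approved symbol, receptor and immunoglobulin segments, HLA genes, pseudogenes, XIST and Y-linked genes were not named. Each list could give up to 2 members that rose and 2 that fell, by smallest adjusted p, or its most abundant member where none was called. For the overlap of comparisons, up to 6 genes per combination of directions were named by the smaller of their absolute log2 fold changes. Marker lists of other cell types gave counts and their most abundant members. Members that lost their call when a library was left out were mostly passed over in the text, a choice made after their values were seen. Some results are withheld and not reported here.

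The groups share replicate numbers. Within each group the deviation of a library from its group mean was correlated across 17815 genes with that of the libraries of the other groups. The 9 correlations between libraries with the same number ran from 0.36 to 0.66, and those between different numbers from -0.43 to -0.14. The numbers were therefore taken to pair the libraries, on the evidence of the data, since the labels do not say what a number marks. The fit with the number as a block is given where it changed a call or moved a count by over 1.5 times.

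The alternatives were RLE and upper quartile normalization, library size only, no filter, a CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, only the groups compared, the replicate block in edgeR and DESeq2, no mitochondrially encoded genes, an adjusted p of 0.01, a 2-fold minimum, and leaving out each library in turn. Scaling by spike-ins, and the replicate block with a loess correction (span 0.3) for GC content and gene length, were added after the data were seen. GC content and length were known for 99.6% of tested genes. Spike-ins took a mean of 0.540% of reads in Tact DMSO, 0.437% in Tex DMSO and 0.490% in Tex mezigdomide. The sources do not say how much spike-in was added or to what, so spike-in scaling cannot be read as RNA per cell.

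The depth leaves sampling noise small: between replicates of a group, chi-square per degree of freedom was 31.5 to 245 and the Pearson correlation of log2 CPM across genes 0.974 to 0.990. The fits were tested on simulated counts with 200 changed genes. Far more genes were called in the data, and the adjustment is stricter where few genes change. The recovered shares therefore hold for the simulation only. For Tex DMSO versus Tact DMSO, 13.4% of genes changed by 1.5-fold, 34.3% by 2-fold and 69.7% by 4-fold were recovered, with 7 false calls among 17500 genes. For Tex mezigdomide versus Tex DMSO these were 6.0%, 43.3% and 72.7%, with 6 among 17522, and for Tex mezigdomide versus Tact DMSO 4.5%, 26.9% and 66.7%, with 6 among 17508. For Tex mezigdomide versus Tex DMSO alone, camera called a planted list and 0 of 40 random lists, with either correlation. Simulated genes were drawn independently of each other, so this cannot show how the list tests behave with correlated genes. Tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.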

Results

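RNA from human T cells was sequenced in 9 libraries that fall into 3 groups of 3. The labels name the groups Tact treated with DMSO, Tex treated with DMSO and Tex treated with mezigdomide, and do not spell out Tact or Tex. The series concerns T cell exhaustion, the loss of function of T cells under lasting stimulation. Mezigdomide binds cereblon, the substrate receptor of a ubiquitin ligase, which then marks the transcription factors Ikaros (IKZF1) and Aiolos (IKZF3) for degradation. DMSO is the solvent alone. A mean of 23742 genes were detected in Tact DMSO, 23349 in Tex DMSO and 23867 in Tex mezigdomide. Levels are given as CPM, counts scaled to the same library total, ± SD and log2 fold changes ± SE, with n = 3 libraries per group in every comparison. A gene is said to rise, fall or change where edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 17815 tested genes gave an adjusted p under 0.05. Counts given as within the list were adjusted over that list alone, and are left out where they were equal. Counts of a list that leaving out 1 library or the replicate number as a block moved by over 1.5 times stand at the end of the paragraph. They are ranges over the libraries left out in turn, unless a single library did so.

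The 3 groups lay apart along the first principal component, which held 59.8% of the variance. Tact DMSO libraries scored -109.7 to -103.4, Tex DMSO 12.6 to 23.9 and Tex mezigdomide 86.5 to 91.2. On the second component, with 14.7% of the variance, Tex DMSO (-67.5 to -43.2) lay apart from Tact DMSO (17.9 to 24.5) and from Tex mezigdomide (29.2 to 38.1). The mean root-mean-square log2 distance was 1.56 between Tact DMSO and Tex mezigdomide libraries, 1.22 between Tact DMSO and Tex DMSO, and 1.06 between Tex DMSO and Tex mezigdomide.

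**Figure D1:**
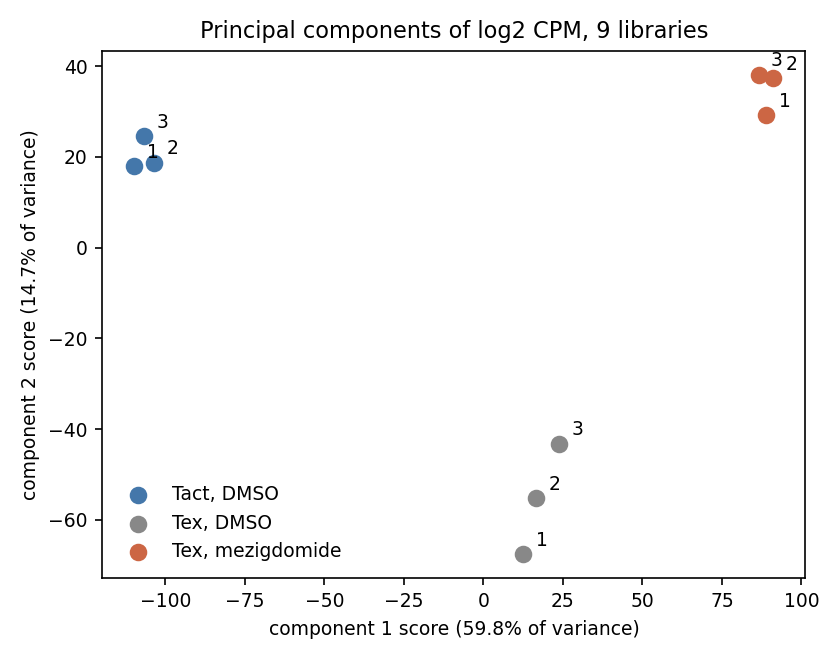
Scores of the 9 libraries on the first and second principal components of log2 CPM, 1 point per library, coloured by group and with the share of variance on each axis. Tex DMSO libraries sit between the other groups on the first component, and apart from both on the second.

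Transcripts of the drug's named targets and of its receptor were measured in each group first. IKZF1 (ENSG00000185811, chromosome 7, 50304068 to 50405101, GENCODE 29 on GRCh38) stood at 229 ± 14.1 CPM in Tact DMSO, 251 ± 12.2 in Tex DMSO and 329 ± 42.8 in Tex mezigdomide. It was not called between the DMSO groups (log2 fold change 0.13 ± 0.10, edgeR adjusted p = 0.348, and 0.0286 to 0.588 over the alternatives, the lowest with spike-in scaling) and rose with the drug (log2 fold change 0.39 ± 0.10, edgeR adjusted p = 0.0315). That rise did not pass without Tex DMSO replicate 1 (edgeR adjusted p = 0.0927), Tex DMSO replicate 2 (0.0823), Tex mezigdomide replicate 1 (0.086) or Tex mezigdomide replicate 2 (0.088), nor with spike-in scaling (0.565), and its lowest adjusted p over the alternatives was 0.0103. IKZF3 (ENSG00000161405, chromosome 17, 39757715 to 39864188) fell from 55.4 ± 5.6 CPM in Tact DMSO to 27.6 ± 7.4 in Tex DMSO (log2 fold change -1.0 ± 0.23, edgeR adjusted p = 0.00798). With the drug it stood at 42.2 ± 11.1 CPM, a difference that missed the threshold (log2 fold change 0.61 ± 0.23, edgeR adjusted p = 0.1) but passed with the replicate number as a block (edgeR adjusted p = 0.0463) or without Tex mezigdomide replicate 3 (0.0413), and ran up to 0.261 over the alternatives. CRBN (ENSG00000113851, chromosome 3, 3144628 to 3179727), which encodes cereblon, stood at 46.9 ± 2.1, 42.3 ± 8.12 and 43.5 ± 2.95 CPM and was not called for Tex DMSO versus Tact DMSO (edgeR adjusted p = 0.392, and 0.0346 without Tex DMSO replicate 2, the lowest of a range up to 0.999) or with the drug (0.876). Transcript levels do not measure the degradation of a protein.

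**Figure D2:**
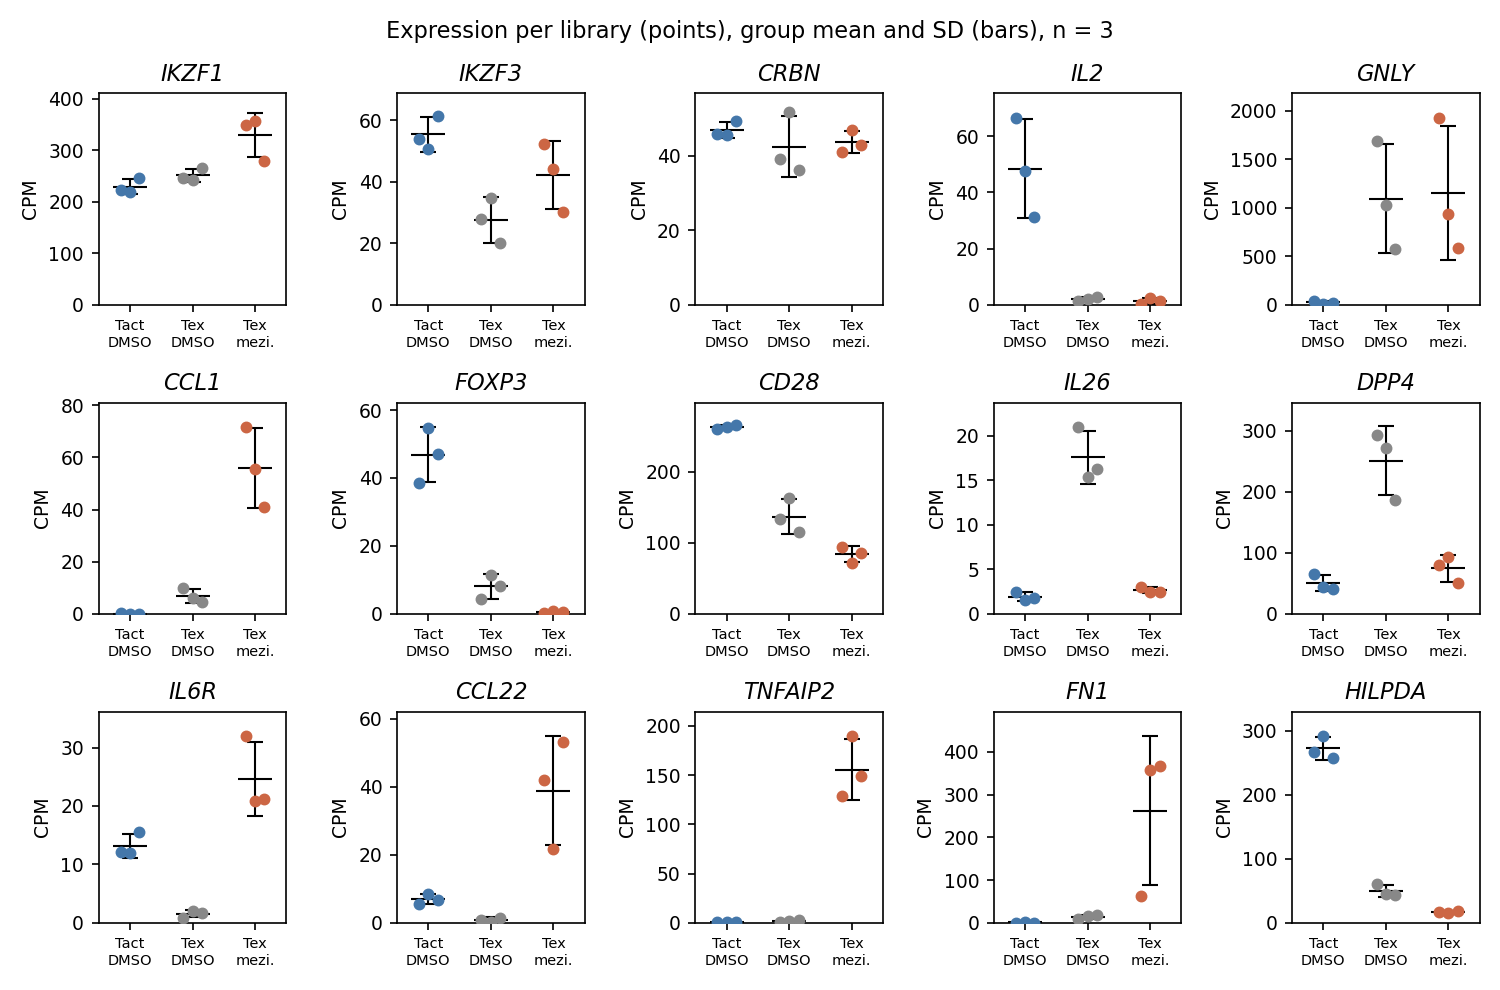
CPM of 15 genes in the 9 libraries, 1 panel per gene and 1 point per library, with the group mean and SD. IKZF1 stood highest in Tex mezigdomide and CRBN at a similar level in all groups, while IL2 and FOXP3 stood highest in Tact DMSO, GNLY was higher in both Tex groups, and TNFAIP2 stood highest in Tex mezigdomide.

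The comparison of Tex DMSO with Tact DMSO asks how the Tex state differs from the Tact state. IL2, the growth cytokine made by stimulated T cells, fell from 48.4 ± 17.5 to 1.99 ± 0.659 CPM (log2 fold change -4.61 ± 0.59, edgeR adjusted p = 0.000436). GNLY, which encodes the cytolytic granule protein granulysin, rose from 24.4 ± 15 to 1094 ± 560.3 CPM (log2 fold change 5.49 ± 0.67, edgeR adjusted p = 0.00036). HAVCR2, which encodes the inhibitory receptor TIM-3, rose from 40.1 ± 4.02 to 180.4 ± 32.8 CPM (log2 fold change 2.17 ± 0.17, edgeR adjusted p = 4.84e-05). TCF7, a transcription factor of naive and memory T cells, fell from 101 ± 7.22 to 27.6 ± 9.58 CPM (log2 fold change -1.87 ± 0.29, edgeR adjusted p = 0.00104). FOXP3, the defining factor of regulatory T cells, fell from 46.8 ± 8.05 to 8.05 ± 3.59 CPM (log2 fold change -2.54 ± 0.39, edgeR adjusted p = 0.00111).

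Of 17815 genes tested, 7329 (41.1%) changed between Tex DMSO and Tact DMSO, 3852 higher and 3477 lower, and 3222 of them by at least 2-fold. The direction split depended on scaling. Higher calls made up 52.6% with TMM, 66.7% (5143 against 2568) with library size only and 85.8% (6169 against 1017) with spike-in scaling. These scalings moved the median log2 fold change of all genes by 0.145 and 0.45, so each change is relative to the bulk of genes. Library values did not overlap between the groups for 54.8% of genes, against 10% by chance if libraries were unpaired. Among genes with a mean log2 CPM of at least 2 and library values that did not overlap, IFI27 (ENSG00000165949, chromosome 14, 94104836 to 94116698) rose most, from 1.77 ± 0.191 to 209 ± 212 CPM (log2 fold change 6.88 ± 1.0, edgeR adjusted p = 0.000805). It was followed by HLX (0.373 to 24.9 ± 6.57 CPM, log2 fold change 6.08 ± 0.27, edgeR adjusted p = 1.05e-05). CXCL11, APOD, GNLY (ENSG00000115523, chromosome 2, 85685175 to 85698854), KLF2, DOCK5 and CXCR6 came next, with log2 fold changes down to 5.33. Within the same limits the named genes that fell most were IL2 (ENSG00000109471, chromosome 4, 122451470 to 122456725), CCL3L3, IL1R2, CALD1, LRATD2, ASS1, NAPSA and IL6R, with log2 fold changes from -4.61 to -3.06. The value of CCL3L3 is uncertain, since it shares reads with near-identical copies.

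Inhibitory receptors mark exhausted T cells. Between Tex DMSO and Tact DMSO, 9 of 22 rose and 5 fell (10 and 5 within the list). The list was not called (camera adjusted p = 0.149). HAVCR2 rose, and so did SIRPG (log2 fold change 1.44 ± 0.13, edgeR adjusted p = 8.45e-05). CD160 stood at 1.1 CPM in Tact DMSO and 0.0846 in Tex DMSO. KLRG1 fell from 1.24 to 0.381 CPM (log2 fold change -1.70 ± 0.35, edgeR adjusted p = 0.00457). With fry the inhibitory receptor list was called higher (adjusted p = 0.00385). For the inhibitory receptor list 3 to 4 fell without 1 library.

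Among exhaustion transcription factors, 7 of 20 rose and 5 fell (7 and 7 within the list), and the list was not called (camera adjusted p = 0.909). Its median log2 fold change of -0.10 had the other sign than its mean of 0.16. The median turned positive with library size only (0.05) and spike-in scaling (0.37). PRDM1 rose from 41.4 ± 6.69 to 119 ± 6.93 CPM (log2 fold change 1.53 ± 0.17, edgeR adjusted p = 0.000254). GFI1 also rose (log2 fold change 0.75 ± 0.09, edgeR adjusted p = 0.000416). IRF4 fell from 629 ± 62.3 to 285 ± 50.9 CPM (log2 fold change -1.14 ± 0.15, edgeR adjusted p = 0.000545). BATF fell (log2 fold change -0.80 ± 0.14, edgeR adjusted p = 0.00176), a call that spike-in scaling ended (edgeR adjusted p = 0.19, the highest of a range from 1.58e-06). Among the naive and memory genes, which mark long-lived T cells, 3 of 22 rose and 9 fell. That list was not called (camera adjusted p = 0.104), and its median of -0.29 became 0.14 with spike-in scaling. KLF2 rose, and so did MYB (log2 fold change 1.85 ± 0.20, edgeR adjusted p = 0.00018). TCF7 fell, and CD28 fell from 263 to 137 CPM (log2 fold change -0.94 ± 0.14, edgeR adjusted p = 0.000826). With fry the naive and memory list was called lower (adjusted p = 0.00385). For the exhaustion factor list 8 fell with the replicate block.

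Cytotoxic effector genes, which encode the contents of killing granules and death ligands, rose as a group in Tex DMSO. In that list 11 of 22 rose and 0 fell. By camera the cytotoxic list had adjusted p = 0.00018, and adjusted p = 0.451 with an estimated correlation. CTSW rose from 36.3 ± 6.63 to 231 ± 34.6 CPM (log2 fold change 2.67 ± 0.18, edgeR adjusted p = 2.46e-05). FASLG rose as well (log2 fold change 2.48 ± 0.27, edgeR adjusted p = 0.000192). Chemokine receptors and homing molecules also rose as a list: 12 of 23 rose and 5 fell. By camera the homing list had adjusted p = 0.000765, and adjusted p = 0.451 with an estimated correlation. ITGA4 rose from 41.6 ± 1.21 to 204 ± 7.99 CPM (log2 fold change 2.30 ± 0.13, edgeR adjusted p = 1.29e-05). SELPLG rose too (log2 fold change 1.75 ± 0.10, edgeR adjusted p = 1.37e-05). CD44 fell from 304 to 97 CPM (log2 fold change -1.65 ± 0.16, edgeR adjusted p = 0.000117). CCR6 fell from 5.63 to 0.168 CPM (log2 fold change -5.06 ± 0.68, edgeR adjusted p = 0.000538). For the cytotoxic list 2 fell with the replicate block.

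Among effector cytokines in Tex DMSO, 6 of 30 rose and 11 fell (7 and 11 within the list). The list was not called (camera adjusted p = 0.0657) except with the replicate block (0.0323, and adjusted p = 0.575 with an estimated correlation), and its median of -0.34 turned positive with spike-in scaling. IL26 rose from 1.93 ± 0.472 to 17.6 ± 3.02 CPM (log2 fold change 3.19 ± 0.22, edgeR adjusted p = 2.77e-05). CSF2, a growth factor for myeloid cells, also rose (log2 fold change 2.43 ± 0.32, edgeR adjusted p = 0.000494). IL17F stood at 31.4 CPM in Tact DMSO and 0.0158 in Tex DMSO, and IL31 at 1.02 and 0.00754. Among the chemokines, 6 of 18 rose and 9 fell (6 and 10 within the list), with camera adjusted p = 0.0657. CXCL13 rose from 5.89 to 36.4 CPM (log2 fold change 2.62 ± 0.45, edgeR adjusted p = 0.00187). CCL1 stood at 0.0649 CPM in Tact DMSO and 6.82 in Tex DMSO. CCL20 fell from 11.5 to 0.633 CPM (log2 fold change -4.18 ± 0.39, edgeR adjusted p = 9.52e-05). XCL2 fell from 5.3 to 0.503 CPM (log2 fold change -3.39 ± 0.39, edgeR adjusted p = 0.000274). With fry the effector cytokine list was called lower (adjusted p = 0.00524) and the chemokine list lower (0.00506).

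Among cytokine receptors, 11 of 27 rose and 10 fell (12 and 11 within the list). They were not called as a list (camera adjusted p = 0.933), with a median of 0.21 and a mean of -0.31. CSF2RB rose from 1.52 to 21.4 CPM (log2 fold change 3.82 ± 0.26, edgeR adjusted p = 2.46e-05). IL12RB2, a receptor chain for interleukin 12, rose from 89.8 to 157 CPM (log2 fold change 0.81 ± 0.08, edgeR adjusted p = 0.000133). IFNGR2 fell from 9.76 to 0.373 CPM (log2 fold change -4.71 ± 0.46, edgeR adjusted p = 0.000121). IL1R1 stood at 26.4 CPM in Tact DMSO and 0.0409 in Tex DMSO. For the cytokine receptor list 7 rose without Tact DMSO replicate 1, and 6 to 9 fell without 1 library.

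Signalling lists held members that moved both ways between the DMSO groups. Among T cell receptor signalling genes, 10 of 32 rose and 8 fell (11 and 9 within the list), with camera adjusted p = 0.804. Among costimulatory receptors and ligands, 7 of 20 rose and 5 fell (8 and 6 within the list), with camera adjusted p = 0.64. CD86 rose from 1.11 to 12 CPM (log2 fold change 3.44 ± 0.27, edgeR adjusted p = 4.35e-05). CD70 rose from 16.8 to 62.1 CPM (log2 fold change 1.88 ± 0.22, edgeR adjusted p = 0.000261). TNFRSF9 fell from 56.1 to 13.5 CPM (log2 fold change -2.06 ± 0.20, edgeR adjusted p = 0.000121). Among the AP-1 family, 3 of 18 rose and 5 fell, with camera adjusted p = 0.294. FOSL2 fell (log2 fold change -1.33 ± 0.14, edgeR adjusted p = 0.000168). Among the NF-kB pathway, 5 of 20 rose and 9 fell (5 and 10 within the list), with camera adjusted p = 0.167. The medians of the T cell receptor, AP-1 and NF-kB lists were -0.01, -0.16 and -0.34, and all 3 turned positive with spike-in scaling. With fry the AP-1 list was called lower (adjusted p = 0.0419) and the NF-kB list lower (0.0154). For the T cell receptor list 5 fell without Tact DMSO replicate 3. For the costimulatory list 2 to 5 fell without 1 library. For the AP-1 list 3 fell without Tact DMSO replicate 2.

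Among NFAT targets and anergy genes, 5 of 22 rose and 5 fell, with camera adjusted p = 0.807. DUSP4 rose from 350.0 to 813 CPM (log2 fold change 1.22 ± 0.12, edgeR adjusted p = 0.000101). LRRC32 fell from 6.31 to 0.346 CPM (log2 fold change -4.19 ± 0.65, edgeR adjusted p = 0.00116). Among the Ikaros family, 1 of 5 rose and 2 fell, with camera adjusted p = 0.707. Among the cereblon pathway and its drug-dependent substrates, 6 of 22 rose and 8 fell (7 and 10 within the list), with camera adjusted p = 0.907. The median of this list was -0.18 and its mean 0.16. The medians of the Ikaros and cereblon lists turned positive with spike-in scaling. For the NFAT list 1 to 3 fell without 1 library, and 8 fell with the replicate block. For the Ikaros list 0 to 1 rose and 1 to 2 fell without 1 library. For the cereblon list 5 to 8 fell without 1 library.

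Among MYC targets and ribosome biogenesis genes in Tex DMSO, 0 of 27 rose and 19 fell. By camera the MYC target list had adjusted p = 1.53e-06, and adjusted p = 0.455 with an estimated correlation. With spike-in scaling the median of -0.47 shrank to -0.01, with 1 higher and 4 lower. MYC fell from 333 ± 4.31 to 100.3 ± 5.78 CPM (log2 fold change -1.73 ± 0.13, edgeR adjusted p = 4.37e-05). Oxidative phosphorylation genes fell relative to the bulk, but their median of -0.40 became 0.02 with spike-in scaling, with 2 higher and 0 lower. With TMM, 0 of 32 rose and 23 fell (0 and 25 within the list). By camera the oxidative phosphorylation list had adjusted p = 1.06e-05, and adjusted p = 0.652 with an estimated correlation. COX7C fell (log2 fold change -0.81 ± 0.07, edgeR adjusted p = 8.72e-05, and 6.45e-19 to 0.126 over the alternatives, the highest with spike-in scaling). For the MYC target list 1 rose with the replicate block.

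Glycolysis and hypoxia genes, which carry sugar breakdown and the low-oxygen response, were lower with TMM, but their median of -0.30 became 0.15 with spike-in scaling, with 8 higher and 5 lower. In this list 1 of 32 rose and 13 fell. By camera the glycolysis list had adjusted p = 0.00891, and adjusted p = 0.676 with an estimated correlation. HILPDA fell from 272 ± 17.4 to 49.6 ± 9.39 CPM (log2 fold change -2.46 ± 0.14, edgeR adjusted p = 1.35e-05). BNIP3 fell too (log2 fold change -1.39 ± 0.16, edgeR adjusted p = 0.00026). Unfolded protein and amino acid stress genes were also lower, with a median of -0.32 that became 0.13 with spike-in scaling, with 5 higher and 4 lower. Among these, 1 of 24 rose and 11 fell. By camera the unfolded protein list had adjusted p = 0.00172, and adjusted p = 0.519 with an estimated correlation. TRIB3 fell from 132 ± 0.549 to 39.5 ± 6.54 CPM (log2 fold change -1.74 ± 0.16, edgeR adjusted p = 8.14e-05). Sterol and fatty acid synthesis genes rose: 13 of 31 rose and 0 fell. With spike-in scaling 26 rose and 0 fell. By camera the sterol list had adjusted p = 0.00201, and adjusted p = 0.687 with an estimated correlation. SQLE, an enzyme of cholesterol synthesis, rose (log2 fold change 1.33 ± 0.18, edgeR adjusted p = 0.000517). For the glycolysis list 1 to 3 rose without 1 library, and 4 rose with the replicate block. For the unfolded protein list 0 to 1 rose without 1 library.

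Among the type I interferon response in Tex DMSO, 7 of 38 rose and 0 fell (6 and 0 within the list). This list was not called (camera adjusted p = 0.0657) except with the replicate block (0.0145, and adjusted p = 0.852 with an estimated correlation, and 0.144 with fry). BST2 rose from 129.8 ± 8.95 to 331 ± 34 CPM (log2 fold change 1.35 ± 0.16, edgeR adjusted p = 0.000327). Among interferon gamma and antigen presentation genes, 6 of 23 rose and 3 fell, with camera adjusted p = 0.569. CD74 rose from 292 to 1116 CPM (log2 fold change 1.94 ± 0.18, edgeR adjusted p = 9.32e-05). IRF8 fell from 219 to 36 CPM (log2 fold change -2.61 ± 0.35, edgeR adjusted p = 0.00058). Among cell cycle genes, 7 of 38 rose and 5 fell (6 and 5 within the list), with camera adjusted p = 0.807. Among the p53 and apoptosis list, 8 of 24 rose and 8 fell, with camera adjusted p = 0.924. CDKN1A rose from 32.2 to 61.5 CPM (log2 fold change 0.93 ± 0.10, edgeR adjusted p = 0.000173). SESN1 fell from 16.7 to 6.22 CPM (log2 fold change -1.42 ± 0.27, edgeR adjusted p = 0.00303). For the type I interferon list 12 rose without Tex DMSO replicate 1, 2 fell without Tex DMSO replicate 2, and 16 rose and 3 fell with the replicate block. For the antigen presentation list 5 fell with the replicate block. For the cell cycle list 3 to 6 rose and 3 to 5 fell without 1 library. For the p53 list 4 to 6 rose and 4 to 6 fell without 1 library.

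Among heat shock genes, 0 of 18 rose and 6 fell (0 and 5 within the list), with a median of -0.30 that turned positive with spike-in scaling. Heat shock genes were not called as a list (camera adjusted p = 0.0657) except with the replicate block (0.0358, and adjusted p = 0.575 with an estimated correlation). HSPD1 fell from 1702 to 732 CPM (log2 fold change -1.22 ± 0.16, edgeR adjusted p = 0.000507). Among histone genes, 1 of 17 rose and 2 fell (0 and 0 within the list), and among mitochondrially encoded genes 0 of 13 rose and 1 fell (0 and 0 within the list). Neither list was called (camera adjusted p = 0.796 and 0.489). For the heat shock list 10 fell with the replicate block. For the histone list 0 rose and 0 to 2 fell without 1 library. For the mitochondrially encoded list 0 to 2 fell without 1 library, and 2 fell with the replicate block.

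Of the helper T cell lists, Th1 and Th17 were called between the DMSO groups. Among Th1 genes, 5 of 12 rose and 1 fell, and HLX rose most among them. By camera the Th1 list had adjusted p = 0.01, and adjusted p = 0.451 with an estimated correlation. Th17 genes fell as a list, with a median of -0.89 and a mean of -3.23: 3 of 13 rose and 7 fell (4 and 7 within the list). By camera the Th17 list had adjusted p = 0.00185, and adjusted p = 0.451 with an estimated correlation. Among Th2 genes, 5 of 15 rose and 4 fell (5 and 5 within the list), with camera adjusted p = 0.765. The Th2 median was 0.17 and the mean -0.14. IL17RB rose from 0.449 to 7.8 CPM (log2 fold change 4.10 ± 0.71, edgeR adjusted p = 0.00197). Among regulatory T cell genes, 5 of 16 rose and 5 fell, with camera adjusted p = 0.909. This test pointed down, with a median of 0.28 and a mean of 0.17. ENTPD1, an ectonucleotidase, rose as FOXP3 fell (log2 fold change 4.34 ± 0.68, edgeR adjusted p = 0.00113). Among gamma delta and innate-like T cell markers, 2 of 8 rose and 2 fell (3 and 2 within the list), with camera adjusted p = 0.807. CEBPD rose from 0.547 to 5.15 CPM (log2 fold change 3.25 ± 0.37, edgeR adjusted p = 0.000252). Median and mean also differed in sign in the gamma delta list (0.41 and -0.24), the NFAT list (0.07 and -0.05) and the histone list (0.01 and -0.15). For the Th1 list 0 to 1 fell without 1 library. For the Th2 list 3 to 5 rose without 1 library. For the regulatory T cell list 3 to 5 rose without 1 library.

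The comparison of Tex mezigdomide with Tex DMSO asks what the drug did to Tex cells. The chemokine CCL22 rose from 0.916 ± 0.635 to 38.8 ± 15.9 CPM (log2 fold change 5.41 ± 0.60, edgeR adjusted p = 0.000781). TNFAIP2, a gene induced by tumour necrosis factor, rose from 1.68 ± 0.558 to 156 ± 30.9 CPM (log2 fold change 6.53 ± 0.28, edgeR adjusted p = 1.56e-05). IL6R, which encodes the receptor chain for interleukin 6, rose from 1.58 ± 0.616 to 24.7 ± 6.32 CPM (log2 fold change 3.96 ± 0.33, edgeR adjusted p = 0.000227). FOXP3 fell from 8.05 ± 3.59 to 0.596 ± 0.31 CPM (log2 fold change -3.76 ± 0.44, edgeR adjusted p = 0.000942), and stood at 46.8 ± 8.05 CPM in Tact DMSO. NKG7, which encodes a granule protein of cytotoxic cells, fell from 166 ± 46.5 to 61.8 ± 15.1 CPM (log2 fold change -1.43 ± 0.22, edgeR adjusted p = 0.00297).

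With the drug 3264 of 17815 genes (18.3%) changed, 1807 higher and 1457 lower, and 1527 by at least 2-fold. With the replicate number as a block 5054 changed, 2685 higher and 2369 lower, and 3260 genes were called by both fits. Without Tex DMSO replicate 1 the count was 2053. Of the calls 55.4% were higher with TMM and 44.7% (767 against 950) with spike-in scaling, which moved the median log2 fold change of all genes by -0.17. Library values did not overlap for 33.4% of genes, against 10% by chance. Within the same abundance and overlap limits, the named genes that rose most were TMEM132A (0.884 to 89.3 ± 13.3 CPM, log2 fold change 6.66 ± 0.51, edgeR adjusted p = 0.000184), TNFAIP2 (ENSG00000185215, chromosome 14, 103123442 to 103137439), TNC (2.88 to 259.8 ± 118 CPM, log2 fold change 6.50 ± 1.0, edgeR adjusted p = 0.00311), CCL22 (ENSG00000102962, chromosome 16, 57358772 to 57366190), FCGBP, COL6A1, FN1 and GSN. FN1 encodes the matrix protein fibronectin and rose from 14 ± 5.05 to 262 ± 174 CPM (log2 fold change 4.23 ± 0.69, edgeR adjusted p = 0.00397). Within these limits those that fell most were FOXP3 (ENSG00000049768, chromosome X, 49250436 to 49264826), HAPLN3 (32.1 to 2.53 CPM, log2 fold change -3.67 ± 0.22, edgeR adjusted p = 7.61e-05), GIMAP1, CRTAM, IL26, KISS1R, RCN3 and GIMAP1-GIMAP5. The GIMAP1 and GIMAP1-GIMAP5 values are uncertain, since the latter is a readthrough gene that shares reads with the former.

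Chemokine genes rose with the drug. In that list 9 of 18 rose and 1 fell (10 and 1 within the list). By camera the chemokines list had adjusted p = 2.99e-08, and adjusted p = 0.105 with an estimated correlation. Monocyte and dendritic cell marker lists were called higher by fry in the same comparison (adjusted p = 0.000817 and 0.0129). CXCL16 rose from 4.98 ± 0.962 to 27.3 ± 4.98 CPM (log2 fold change 2.45 ± 0.20, edgeR adjusted p = 0.000206). CCL20, which attracts lymphocytes, rose (log2 fold change 3.57 ± 0.38, edgeR adjusted p = 0.000634). CCL17 stood at 0.0347 CPM in Tex DMSO and 16.4 ± 5.87 in Tex mezigdomide. Effector cytokines moved apart: 6 of 30 rose and 4 fell (6 and 8 within the list). That list was not called (camera adjusted p = 0.583), with a median that rounded to 0, a mean of 0.12 and a test that pointed down. CSF2 rose from 25.5 ± 9.38 to 80.5 ± 23.9 CPM (log2 fold change 1.66 ± 0.31, edgeR adjusted p = 0.00689). IL26 fell from 17.6 ± 3.02 to 2.67 ± 0.317 CPM (log2 fold change -2.72 ± 0.22, edgeR adjusted p = 0.000206). IL16 fell from 88.3 to 44.6 CPM (log2 fold change -0.99 ± 0.14, edgeR adjusted p = 0.00186). IL6 stood at 0.00392 CPM in Tex DMSO and 1.43 with the drug. IL2 did not pass the test between the Tex groups (1.99 and 1.42 CPM, edgeR adjusted p = 0.587). For the chemokine list 0 to 1 fell without 1 library, and 3 fell with the replicate block. For the effector cytokine list 9 fell with the replicate block.

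Among cytokine receptors, 5 of 27 rose and 3 fell (8 and 7 within the list), with camera adjusted p = 0.279. IL13RA1 rose from 2.26 to 10.6 CPM (log2 fold change 2.22 ± 0.23, edgeR adjusted p = 0.000563). IL2RG, the receptor chain shared by several cytokines, fell from 588 to 391 CPM (log2 fold change -0.59 ± 0.08, edgeR adjusted p = 0.0017). IL23R fell from 12.8 to 6.75 CPM (log2 fold change -0.92 ± 0.15, edgeR adjusted p = 0.00377). For the cytokine receptor list 3 rose without Tex DMSO replicate 1, 5 fell without Tex DMSO replicate 1, and 11 rose and 6 fell with the replicate block.

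The cytotoxic effector list was called lower with the drug. In that list 0 of 22 rose and 6 fell (0 and 7 within the list). By camera the cytotoxic list had adjusted p = 0.0128, and adjusted p = 0.519 with an estimated correlation. NKG7 fell, and GZMK fell from 3.39 to 0.644 CPM (log2 fold change -2.39 ± 0.38, edgeR adjusted p = 0.00336). Among inhibitory receptors, 2 of 22 rose and 4 fell (2 and 8 within the list). The list was not called (camera adjusted p = 0.0601) except with the replicate block (0.0323, and adjusted p = 0.542 with an estimated correlation). CD200 rose from 19.8 to 68 CPM (log2 fold change 1.78 ± 0.19, edgeR adjusted p = 0.000566). PVRIG fell from 23.9 to 5.72 CPM (log2 fold change -2.06 ± 0.21, edgeR adjusted p = 0.000532). Among exhaustion transcription factors, 2 of 20 rose and 3 fell (2 and 6 within the list), with camera adjusted p = 0.322. SNX9 fell from 109.7 to 53.9 CPM (log2 fold change -1.02 ± 0.20, edgeR adjusted p = 0.00841). NFATC2 rose (log2 fold change 0.71 ± 0.13, edgeR adjusted p = 0.00605, and 2.41e-05 to 0.183 over the alternatives, the highest with spike-in scaling). With fry the inhibitory receptor list was called lower (adjusted p = 0.00946). For the cytotoxic list 1 rose without Tex DMSO replicate 3, 3 to 7 fell without 1 library, and 10 fell with the replicate block. For the inhibitory receptor list 1 to 2 rose without 1 library, 2 fell without Tex DMSO replicate 1, and 8 fell with the replicate block. For the exhaustion factor list 1 to 3 rose without 1 library, 1 fell without Tex mezigdomide replicate 1, and 7 fell with the replicate block.

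Among naive and memory genes, 5 of 22 rose and 4 fell (6 and 4 within the list), with camera adjusted p = 0.909. IL7R rose from 90.6 ± 28.3 to 279 ± 68.9 CPM (log2 fold change 1.62 ± 0.27, edgeR adjusted p = 0.00461). ACTN1 rose as well (log2 fold change 1.75 ± 0.23, edgeR adjusted p = 0.00173). CD28 fell from 137 to 84 CPM (log2 fold change -0.70 ± 0.14, edgeR adjusted p = 0.00875). ID3 fell from 7.42 to 1.92 CPM (log2 fold change -1.95 ± 0.24, edgeR adjusted p = 0.00114). Among chemokine receptors and homing molecules, 3 of 23 rose and 4 fell (4 and 4 within the list), with camera adjusted p = 0.879. Its mean was -0.12, and its median of 0.10 turned negative with spike-in scaling. ITGB1 rose from 133 to 308 CPM (log2 fold change 1.21 ± 0.14, edgeR adjusted p = 0.000869). For the naive and memory list 3 to 5 rose without 1 library. For the homing list 1 to 3 fell without 1 library.

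The regulatory T cell list was called lower with the drug: 0 of 16 rose and 6 fell (0 and 8 within the list). By camera the regulatory T cell list had adjusted p = 0.0113, and adjusted p = 0.455 with an estimated correlation. FOXP3 fell, and IL2RA fell from 942 to 515 CPM (log2 fold change -0.87 ± 0.16, edgeR adjusted p = 0.00703). Among costimulatory genes, 0 of 20 rose and 6 fell (2 and 6 within the list), with camera adjusted p = 0.269. The list's mean was -0.18, and its median of 0.07 turned negative with spike-in scaling. CRTAM fell from 11.4 to 1.72 CPM (log2 fold change -2.73 ± 0.46, edgeR adjusted p = 0.00452). Among T cell receptor signalling genes, 1 of 32 rose and 5 fell, with camera adjusted p = 0.278. LCK fell from 411 to 267 CPM (log2 fold change -0.62 ± 0.11, edgeR adjusted p = 0.00567). PLCG1 fell from 166 to 98.5 CPM (log2 fold change -0.75 ± 0.11, edgeR adjusted p = 0.00231). Among NFAT targets and anergy genes, 2 of 22 rose and 4 fell, with camera adjusted p = 0.744. RCAN1 rose from 15.3 to 74.6 CPM (log2 fold change 2.29 ± 0.33, edgeR adjusted p = 0.00227). DUSP4 fell from 813 to 449.9 CPM (log2 fold change -0.85 ± 0.11, edgeR adjusted p = 0.00167). With fry the costimulatory list was called lower (adjusted p = 0.0325). For the regulatory T cell list 1 rose without Tex DMSO replicate 3, 3 fell without Tex mezigdomide replicate 3, and 1 rose with the replicate block. For the costimulatory list 2 rose without Tex DMSO replicate 3, and 3 rose with the replicate block. For the T cell receptor list 0 to 2 rose and 2 to 5 fell without 1 library, and 4 rose and 11 fell with the replicate block. For the NFAT list 1 to 3 rose and 2 to 4 fell without 1 library, and 6 rose with the replicate block.

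With the drug, in the AP-1 list 4 of 18 rose and 2 fell (4 and 3 within the list), in the NF-kB list 5 of 20 rose and 1 fell, in the Ikaros list 1 of 5 rose and 0 fell, in the cereblon list 2 of 22 rose and 1 fell (1 and 0 within the list) and in the p53 list 1 of 24 rose and 1 fell (1 and 0 within the list). In the heat shock list 0 of 18 rose and 2 fell, in the Th1 list 1 of 12 rose and 1 fell (2 and 1 within the list), in the Th2 list 0 of 15 rose and 1 fell (0 and 0 within the list), in the Th17 list 2 of 13 rose and 2 fell and in the gamma delta list 1 of 8 rose and 2 fell. Camera called none of these lists (adjusted p = 0.065 to 0.879). With fry the NF-kB list was called higher (adjusted p = 0.0129) and the Ikaros list higher (0.00693). For the AP-1 list 0 to 2 fell without 1 library. For the NF-kB list 0 to 1 fell without 1 library. For the Ikaros list 0 to 2 rose without 1 library, and 3 rose with the replicate block. For the cereblon list 0 to 2 rose and 0 to 1 fell without 1 library. For the p53 list 1 to 2 rose and 0 to 2 fell without 1 library, and 2 rose and 2 fell with the replicate block. For the heat shock list 0 to 4 fell without 1 library, and 5 fell with the replicate block. For the Th1 list 0 to 3 rose and 0 to 1 fell without 1 library, and 4 rose with the replicate block. For the Th2 list 0 to 4 fell without 1 library, and 6 fell with the replicate block. For the Th17 list 1 to 2 rose without 1 library. For the gamma delta list 1 to 2 fell without 1 library, and 2 rose with the replicate block.

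Glycolysis and hypoxia genes fell with the drug. In that list 0 of 32 rose and 20 fell (1 and 26 within the list). By camera the glycolysis list had adjusted p = 3.99e-13, and adjusted p = 0.451 with an estimated correlation. ALDOC fell from 288 ± 16.4 to 118 ± 20.8 CPM (log2 fold change -1.28 ± 0.12, edgeR adjusted p = 0.000373). HILPDA fell (log2 fold change -1.52 ± 0.14, edgeR adjusted p = 0.000289). Sterol and fatty acid synthesis genes fell as well: 0 of 31 rose and 17 fell (1 and 19 within the list). By camera the sterol list had adjusted p = 4.32e-07, and adjusted p = 0.519 with an estimated correlation. HMGCS1 fell from 269.7 ± 34 to 162 ± 28.5 CPM (log2 fold change -0.73 ± 0.14, edgeR adjusted p = 0.00807). EBP, another enzyme of cholesterol synthesis, fell (log2 fold change -0.84 ± 0.13, edgeR adjusted p = 0.00292). Among MYC targets and ribosome biogenesis genes, 0 of 27 rose and 10 fell (0 and 13 within the list). By camera the MYC target list had adjusted p = 6.49e-05, and adjusted p = 0.519 with an estimated correlation. IMPDH2 fell from 207 ± 49.4 to 100.4 ± 27.3 CPM (log2 fold change -1.04 ± 0.22, edgeR adjusted p = 0.0123). For the glycolysis list 1 rose with the replicate block. For the sterol list 11 to 16 fell without 1 library, and 1 rose with the replicate block. For the MYC target list 5 to 12 fell without 1 library.

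The cell cycle list was called lower with the drug, although few members passed: 0 of 38 rose and 7 fell (0 and 8 within the list). By camera the cell cycle list had adjusted p = 1.74e-05, and adjusted p = 0.687 with an estimated correlation. With fry the cell cycle list was not called (adjusted p = 0.076). E2F1 fell from 67.7 to 42 CPM (log2 fold change -0.69 ± 0.12, edgeR adjusted p = 0.00502). E2F8 fell from 30.8 to 20.5 CPM (log2 fold change -0.59 ± 0.13, edgeR adjusted p = 0.0157). The cell cycle inhibitor CDKN1A rose from 61.5 to 145 CPM (log2 fold change 1.24 ± 0.10, edgeR adjusted p = 0.000206). For the cell cycle list 2 to 13 fell without 1 library, and 15 fell with the replicate block.

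Camera called the mitochondrial lists lower with the drug, although few members passed. Among oxidative phosphorylation genes, 1 of 32 rose and 4 fell (0 and 3 within the list). By camera the oxidative phosphorylation list had adjusted p = 0.0146, and adjusted p = 0.798 with an estimated correlation. The list was not called without Tex DMSO replicate 1 (camera adjusted p = 0.143) or Tex mezigdomide replicate 2 (0.0652), nor with fry (adjusted p = 0.109). NDUFV1, a subunit of the first respiratory complex, fell (log2 fold change -0.55 ± 0.12, edgeR adjusted p = 0.0118). Among mitochondrially encoded genes, 0 of 13 rose and 1 fell (0 and 0 within the list). By camera the mitochondrial list had adjusted p = 0.00891, and adjusted p = 0.687 with an estimated correlation. That list was not called without Tex DMSO replicate 3 (camera adjusted p = 0.137), nor with fry (adjusted p = 0.128). For the oxidative phosphorylation list 0 rose and 1 to 3 fell without 1 library. For the mitochondrially encoded list 0 to 9 fell without 1 library, and 9 fell with the replicate block.

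The interferon gamma and antigen presentation list was called higher with the drug: 6 of 23 rose and 0 fell (8 and 0 within the list). By camera the antigen presentation list had adjusted p = 0.00824, and adjusted p = 0.519 with an estimated correlation. TAP2 rose from 151 ± 10.9 to 295 ± 9.12 CPM (log2 fold change 0.96 ± 0.09, edgeR adjusted p = 0.000284). CD74 rose (log2 fold change 1.53 ± 0.18, edgeR adjusted p = 0.000931). Of 38 type I interferon response genes 0 were called in edgeR, with 3 higher and 0 lower at an unadjusted p under 0.05. DESeq2 called 3 higher, limma-voom 2 and the replicate block 8. In edgeR 2 rose without Tex DMSO replicate 2 or Tex mezigdomide replicate 1. That list was not called (camera adjusted p = 0.187) except with the replicate block (0.0431, and adjusted p = 0.89 with an estimated correlation, and 0.37 with fry). Among unfolded protein and amino acid stress genes, 2 of 24 rose and 4 fell, with camera adjusted p = 0.48. SHMT2 fell from 332 to 194 CPM (log2 fold change -0.77 ± 0.12, edgeR adjusted p = 0.00301). For the antigen presentation list 3 to 6 rose without 1 library, and 1 fell with the replicate block. For the unfolded protein list 0 to 3 rose without 1 library, and 2 fell without Tex DMSO replicate 3.

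**Figure D3:**
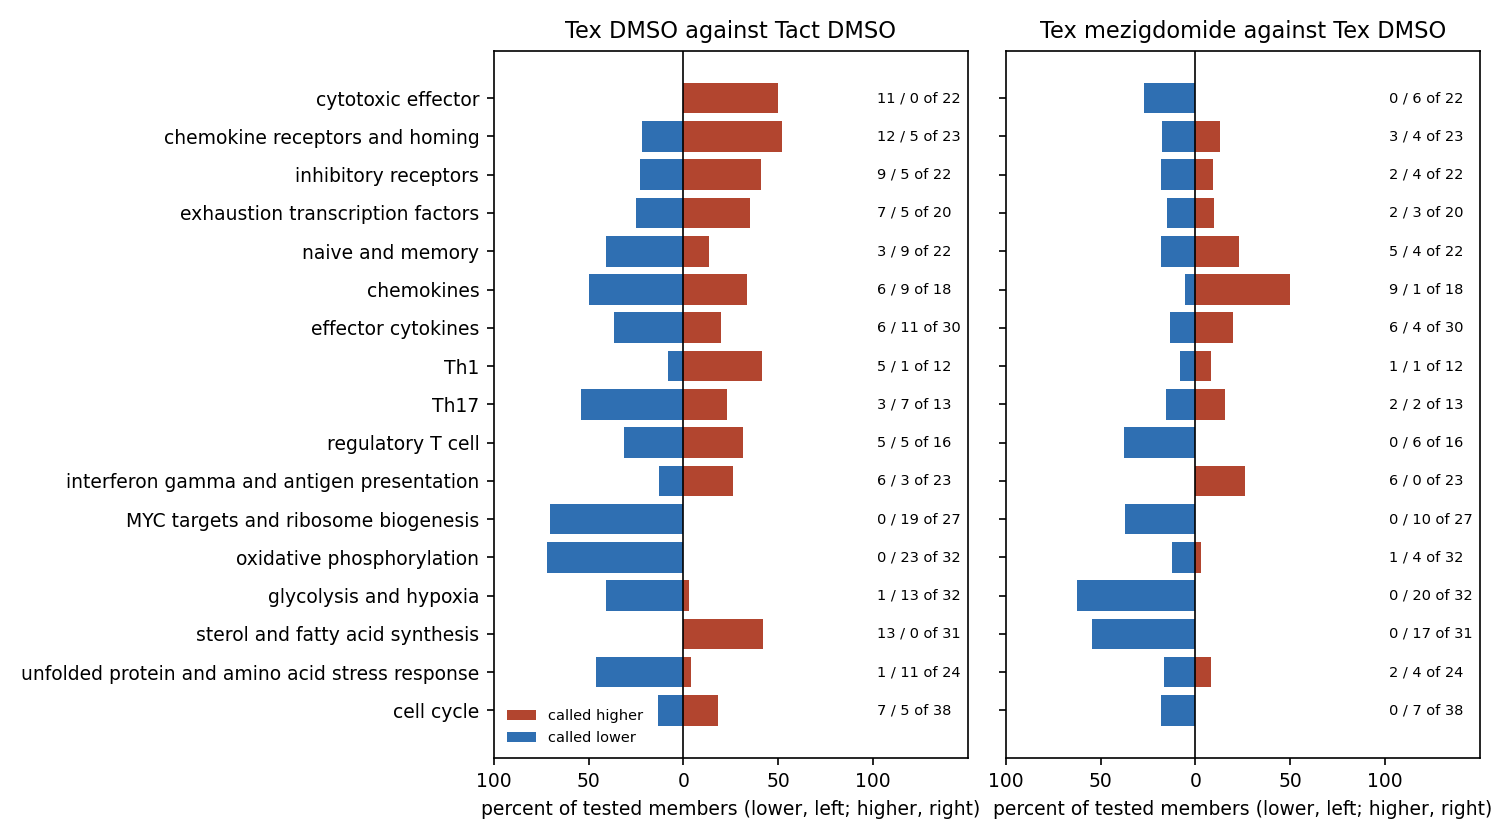
Percent of the tested members of 17 gene lists called higher or lower, in bars from 0, for Tex DMSO versus Tact DMSO and for Tex mezigdomide versus Tex DMSO. In Tex DMSO more glycolysis, oxidative phosphorylation and unfolded protein genes were lower than higher, with medians that changed sign with spike-in scaling. Of 31 sterol genes 13 rose in Tex DMSO and 17 fell with the drug.

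The comparison of Tex mezigdomide with Tact DMSO asks how far drug-treated Tex cells stood from the Tact state. FOXP3 fell further from the Tact level, from 46.8 ± 8.05 to 0.596 ± 0.31 CPM (log2 fold change -6.30 ± 0.48, edgeR adjusted p = 1.32e-05), and IL2 fell (log2 fold change -5.10 ± 0.60, edgeR adjusted p = 0.00013). HILPDA, a lipid droplet gene induced in low oxygen, fell from 272 ± 17.4 to 17.2 ± 1.65 CPM (log2 fold change -3.98 ± 0.15, edgeR adjusted p = 1.66e-06). TNFAIP2 (log2 fold change 7.97 ± 0.30, edgeR adjusted p = 1.66e-06) and CXCL11 (log2 fold change 10.03 ± 1.60, edgeR adjusted p = 0.0007) were higher than in Tact DMSO. IKZF1 rose from 229 ± 14.1 to 329 ± 42.8 CPM (log2 fold change 0.52 ± 0.10, edgeR adjusted p = 0.00244), whereas IKZF3 and CRBN were not called (edgeR adjusted p = 0.176 and 0.496).

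More genes changed in this comparison than in either of the others: 10009 of 17815 (56.2%), 5258 higher and 4751 lower, and 5242 by at least 2-fold. Library values did not overlap for 65.3% of genes, against 10% by chance. Of the calls 52.5% were higher with TMM, 62.6% with library size only and 71.2% (5730 against 2323) with spike-in scaling, which moved the median of all genes by 0.154 and 0.278. After CXCL11, the named genes within those limits that rose most were FN1 (log2 fold change 8.12 ± 0.84, edgeR adjusted p = 6.24e-05), TNFAIP2, IFI27, TNC, DOCK5, ITGA9 and UBD. Below FOXP3 and IL2, those that fell most were ASS1, ADTRP, HAPLN3, GIMAP1, HILPDA and SERPINA1, with log2 fold changes of -4.77 to -3.90.

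The 6 lists in this paragraph were called lower in Tex mezigdomide than in Tact DMSO. Among MYC targets and ribosome biogenesis genes, 0 of 27 rose and 25 fell. By camera the MYC target list had adjusted p = 4.58e-09, and adjusted p = 0.451 with an estimated correlation. Among glycolysis and hypoxia genes, 2 of 32 rose and 25 fell. By camera the glycolysis list had adjusted p = 4.58e-09, and adjusted p = 0.451 with an estimated correlation. Among oxidative phosphorylation genes, 0 of 32 rose and 24 fell. By camera the oxidative phosphorylation list had adjusted p = 1.53e-06, and adjusted p = 0.614 with an estimated correlation. Among unfolded protein and amino acid stress genes, 4 of 24 rose and 12 fell. By camera the unfolded protein list had adjusted p = 0.00623, and adjusted p = 0.519 with an estimated correlation. Among heat shock genes, 0 of 18 rose and 8 fell. By camera the heat shock list had adjusted p = 0.0286, and adjusted p = 0.652 with an estimated correlation. Among mitochondrially encoded genes, 0 of 13 rose and 10 fell (0 and 12 within the list). By camera the mitochondrial list had adjusted p = 0.0488, and adjusted p = 0.798 with an estimated correlation. That call was lost without Tact DMSO replicate 1 (camera adjusted p = 0.0614), Tact DMSO replicate 3 (0.0566), Tex mezigdomide replicate 1 (0.0614) or Tex mezigdomide replicate 2 (0.0626). With spike-in scaling 19 glycolysis, 12 MYC, 8 oxidative phosphorylation and 0 mitochondrially encoded genes fell, and the medians of all 6 lists stayed negative. For the MYC target list 1 rose with the replicate block. For the glycolysis list 1 to 2 rose without 1 library. For the heat shock list 1 rose without Tex mezigdomide replicate 2, 5 fell without Tact DMSO replicate 1, and 1 rose with the replicate block. For the mitochondrially encoded list 4 to 11 fell without 1 library.

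Of 31 sterol and fatty acid synthesis genes 9 rose and 10 fell against Tact DMSO. That list was not called (camera adjusted p = 0.88). Its mean was 0.23, and its median of -0.09 turned positive with library size only and spike-in scaling. Th1 genes rose: 6 of 12 rose and 0 fell. By camera the Th1 list had adjusted p = 0.0108, and adjusted p = 0.451 with an estimated correlation. Th17 genes fell: 2 of 13 rose and 8 fell. By camera the Th17 list had adjusted p = 0.00878, and adjusted p = 0.451 with an estimated correlation. Homing genes rose on balance: 13 of 23 rose and 7 fell (14 and 7 within the list). By camera the homing list had adjusted p = 0.0108, and adjusted p = 0.451 with an estimated correlation. Among type I interferon response genes, 15 of 38 rose and 0 fell (14 and 0 within the list). By camera the type I interferon response list had adjusted p = 0.0339, and adjusted p = 0.905 with an estimated correlation. Without Tex mezigdomide replicate 2 it was not called (camera adjusted p = 0.225), nor was it with fry (adjusted p = 0.181). For the Th1 list 1 fell without Tex mezigdomide replicate 2, and 1 fell with the replicate block. For the Th17 list 1 rose without Tex mezigdomide replicate 1. For the type I interferon list 9 rose without Tact DMSO replicate 1, 2 fell without Tex mezigdomide replicate 2, and 2 fell with the replicate block.

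Among cytotoxic genes against Tact DMSO, 11 of 22 rose and 6 fell (11 and 7 within the list). The cytotoxic list was not called (camera adjusted p = 0.221). Among inhibitory receptors, 7 of 22 rose and 5 fell, with camera adjusted p = 0.907. Among exhaustion transcription factors, 6 of 20 rose and 7 fell, with camera adjusted p = 0.744. Among regulatory T cell genes, 4 of 16 rose and 7 fell (5 and 8 within the list), with camera adjusted p = 0.228. Among effector cytokines, 7 of 30 rose and 12 fell (7 and 13 within the list), and the list was called lower by camera only with the replicate block (camera adjusted p = 0.0657, and with the block 0.0364, and adjusted p = 0.597 with an estimated correlation). Among chemokines, 10 of 18 rose and 6 fell, and the list was called higher by camera only with the replicate block (camera adjusted p = 0.294, and with the block 0.0447, and adjusted p = 0.597 with an estimated correlation). The other 22 of the 39 lists were not called, each with a camera adjusted p of at least 0.0657. Of these the naive and memory, B cell and red cell lists were called lower with fry, and the antigen presentation, monocyte, dendritic cell and stromal lists higher (adjusted p = 0.000582 to 0.0312). With fry the cytotoxic list was called higher (adjusted p = 0.0139), the regulatory T cell list lower (0.0139), the effector cytokine list lower (0.00297) and the chemokine list higher (0.00542). For the inhibitory receptor list 8 fell with the replicate block.

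Both comparisons were set side by side to ask whether the drug moved the Tex pattern back. DPP4, a surface peptidase, stood at 50.4 ± 13.5 CPM in Tact DMSO, 251 ± 56.4 in Tex DMSO and 74.7 ± 22.3 in Tex mezigdomide, so it rose in Tex cells and fell with the drug (log2 fold change -1.75 ± 0.27, edgeR adjusted p = 0.00339). IL6R went the other way, at 13.2 ± 2.04, 1.58 ± 0.616 and 24.7 ± 6.32 CPM. UBD rose in both steps, from 0.811 ± 0.462 to 8.33 ± 6.9 and 90.8 ± 6.91 CPM. ADTRP fell in both, from 49.2 ± 4.46 to 9.43 ± 2.9 and 1.95 ± 0.687 CPM.

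Of all tested genes 531 were called in opposite directions by the comparisons, 253 higher in Tex DMSO and lower with the drug and 278 the reverse, while independent lists of these sizes would share 315 and 352.7. In the same direction 1239 were called, 672 higher in both and 567 lower in both, against 390.7 and 284.4. With the replicate block 954 were called in opposite directions and 2149 in the same. The opposite count was 338 without Tact DMSO replicate 1, 352 without Tact DMSO replicate 2, 334 without Tact DMSO replicate 3 and 313 without Tex DMSO replicate 1, and the same-direction count was 726 without Tex DMSO replicate 1. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.11 and a Spearman correlation of 0.207. Both comparisons use the Tex DMSO libraries, and in 40 simulations of unchanged groups this alone gave a Pearson correlation of -0.506 and 0 genes called by both. These simulations drew all libraries independently and left out the pairing by number, so -0.506 need not hold for these data. After DPP4, genes that rose and then fell included IL26, F2R (4.1, 18.4 and 3.83 CPM), ABCA2 and PIK3R6. LSR (21.3, 4.24 and 24.7 CPM), CCL22 and APBA2 fell and then rose. FN1, TMEM200A, RASSF4 and FXYD6 rose in both, and FOXP3, PRR7, RRAGD and SERPINA1 fell in both.

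**Figure D4:**
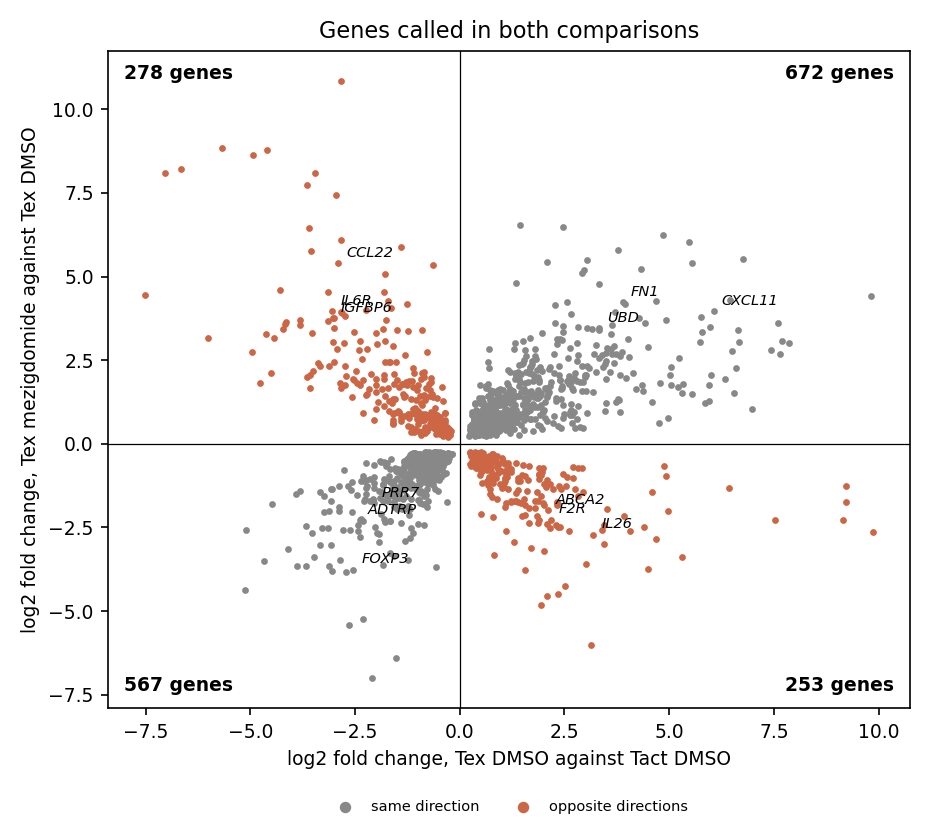
Log2 fold change with the drug (vertical axis) against that of Tex DMSO versus Tact DMSO (horizontal axis), 1 point per gene called in both comparisons, coloured by whether the directions were the same or opposite. With TMM scaling, the 1239 genes called in the same direction outnumber the 531 called in opposite directions.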

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

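Spike-in scaling and the replicate block with GC and length correction were chosen after the data were seen, and the predictions for other splits of the libraries were written after the result. The other settings were planned. Leaving out each library in turn called 5495 to 6777 genes for Tex DMSO versus Tact DMSO, 2053 to 2839 for Tex mezigdomide versus Tex DMSO, 8557 to 9553 for Tex mezigdomide versus Tact DMSO, and 313 to 452 genes in opposite directions by the first and second of these. Fewer libraries and a lower adjusted p call fewer genes by construction. At an adjusted p of 0.01 the first comparison called 4469 genes, the second 1291, and 142 were opposite and 358 in the same direction. At least 2-fold changes numbered 3222, 1527 and 5242.

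For Tex mezigdomide versus Tex DMSO, fitting only the 6 libraries compared called 1946 genes, the replicate block 5054, the replicate block in DESeq2 5208, the replicate block with GC and length correction 5306, and spike-in scaling 1717. Opposite genes numbered 954 with the replicate block and 349 with spike-in scaling, and genes in the same direction 2149 and 460, with 726 without Tex DMSO replicate 1. The block takes the shared deviation of same-numbered libraries out of the spread. The cause of the lower counts with spike-in scaling and with 6 libraries was not tested. Every other count of called, opposite or same-direction genes here lay within 1.5 times of the reported one. List members are counted with their lists. The block also called IKZF3 between the Tex groups, and 9 lists given with their comparisons; it changed no other call reported here. None of those 9 was called with an estimated correlation.

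Of 418 values of named genes, 415 kept their direction and side of the threshold in DESeq2, 414 with RLE, 409 with library size only, 405 without a filter and 359 with spike-in scaling. Leaving out 1 library kept 2307 of 2508 and made 195 weaker. CRBN changed sign for Tex DMSO versus Tact DMSO with spike-in scaling (log2 fold change 0.291), as did IKZF5 (0.114) and MT-CO3 (0.033). For Tex mezigdomide versus Tex DMSO, CRBN changed sign with spike-in scaling (-0.11) and without Tex DMSO replicate 1 (-0.013), Tex mezigdomide replicate 2 (-0.016) or Tex DMSO replicate 3 (-0.063), with up to 0.204 without another library. For Tex mezigdomide versus Tact DMSO it did so with library size only (0.046) and spike-in scaling (0.181). None of these values passed the test, and the cause was not tested.

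No list call of the 30 held with an estimated correlation. All 30 held with RLE and with the replicate block, 26 passed fry (not the cell cycle, oxidative phosphorylation and mitochondrial lists with the drug, nor the type I interferon list for Tex mezigdomide versus Tact DMSO), and 9 of 180 calls were lost when 1 library was left out. Of the 87 tests of lists not called, 30 passed fry, each named with its comparison. Depth sets no limit on the abundant genes, where replicates differed by more than sampling noise; genes at a few reads are given as levels without a fold.

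The real grouping was set against the other ways to part the 6 libraries of each comparison, 10 splits in each. The real split called 7329 genes for Tex DMSO versus Tact DMSO, 3264 for Tex mezigdomide versus Tex DMSO and 10009 for Tex mezigdomide versus Tact DMSO, and the highest other called 0, both among the 3 others that part all 3 pairs and among the 6 that part fewer. Only 1 of 10 splits, the real one, was as large in each, and 10 splits are too few for a share under 0.05.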

Other observations

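The marker genes and tests of the 3 patterns weighed in this part were chosen after the result was seen, except those of the ribosomal protein genes, which were written before their outcome. The marker lists were fixed beforehand, but the genes named from those of other cell types, and the ribosomal protein genes as a pattern, were chosen after their values were seen.

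Genes of the B cell lineage moved apart with the drug. CR2 stood at 0.0389 CPM in Tex DMSO and 3.54 in Tex mezigdomide. PAX5, the B cell identity factor, rose at each step, from 1.57 ± 0.592 to 3.92 ± 0.755 and 15.1 ± 5.53 CPM (with the drug log2 fold change 1.94 ± 0.34, edgeR adjusted p = 0.00544). CD22 fell with the drug from 6.74 ± 3.61 to 0.316 ± 0.212 CPM (log2 fold change -4.40 ± 0.66, edgeR adjusted p = 0.00274), and CD79B fell (log2 fold change -0.78 ± 0.12, edgeR adjusted p = 0.00361). CD79A fell from 8.99 to 1.44 CPM (log2 fold change -2.64 ± 0.26, edgeR adjusted p = 0.000127) in Tex DMSO versus Tact DMSO. The list of B cell markers had 1 higher and 3 lower of 10 (camera adjusted p = 0.209) in that comparison and 2 higher and 3 lower of 10 (camera adjusted p = 0.623) with the drug, with a median of -0.23 and a mean of 0.15. Plasma cell markers had 4 higher and 0 lower of 4 (camera adjusted p = 0.0657) in the first comparison. With the drug 0 of 4 rose and 1 fell, and the call of the list (camera adjusted p = 0.0167, and adjusted p = 0.451 with an estimated correlation) ended without Tex DMSO replicate 3 (0.0503). MZB1 fell from 28.5 ± 2.78 to 6.57 ± 2.2 CPM (log2 fold change -2.12 ± 0.23, edgeR adjusted p = 0.000634). With fry the B cell list was called lower between the DMSO groups (adjusted p = 0.00989) and the plasma cell list higher between the DMSO groups (0.000582). For the plasma cell list, between the DMSO groups, 2 to 3 rose without 1 library.

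Some T cells also carry receptors of natural killer cells. NCAM1 (0.26 to 5.88 CPM, log2 fold change 4.50 ± 0.61, edgeR adjusted p = 0.0006) and KIR2DL4 (0.105 to 1.45 CPM, log2 fold change 3.75 ± 0.40, edgeR adjusted p = 0.00018) rose in Tex DMSO. With the drug NCR3 fell from 12.6 to 2.92 CPM (log2 fold change -2.10 ± 0.27, edgeR adjusted p = 0.00134). The NK list had 7 higher and 2 lower of 16 (camera adjusted p = 0.312) between the DMSO groups and 0 higher and 4 lower of 16 (1 and 4 within the list, camera adjusted p = 0.369) with the drug. Monocyte and macrophage markers had 2 higher and 0 lower of 9 (camera adjusted p = 0.648) between the DMSO groups and 2 higher and 0 lower of 9 (camera adjusted p = 0.0622) with the drug. Dendritic cell markers had 2 higher and 0 lower of 5 (2 and 1 within the list, camera adjusted p = 0.843) and 1 higher and 0 lower of 5 (camera adjusted p = 0.083) in the same order. Both were called with the drug under the replicate block (0.0225 each, and adjusted p = 0.542 with an estimated correlation). Red cell and platelet markers had 0 higher and 2 lower of 4 (camera adjusted p = 0.448) and 0 higher and 1 lower of 4 (camera adjusted p = 0.527). Stromal and epithelial markers had 1 higher and 3 lower of 9 (camera adjusted p = 0.796) and 1 higher and 0 lower of 9 (camera adjusted p = 0.209). Histone genes had 5 higher and 1 lower of 17 (7 and 1 within the list, camera adjusted p = 0.0657) with the drug. H2AC6 rose (log2 fold change 1.44 ± 0.22, edgeR adjusted p = 0.00301). With fry the NK list was called higher between the DMSO groups (adjusted p = 0.0455), the monocyte list higher between the DMSO groups (0.0129), the red cell list lower between the DMSO groups (0.0405), the monocyte list higher with the drug (0.000817), the dendritic cell list higher with the drug (0.0129), the stromal list higher with the drug (0.00265) and the histone list higher with the drug (0.0259). For the NK list, with the drug, 1 rose without Tex DMSO replicate 1, and 2 rose with the replicate block. For the monocyte list, between the DMSO groups, 1 to 3 rose without 1 library, and 4 rose and 1 fell with the replicate block. For the dendritic cell list, between the DMSO groups, 1 to 2 rose without 1 library, 1 fell without Tex DMSO replicate 2, and 1 fell with the replicate block. For the dendritic cell list, with the drug, 2 rose without Tex DMSO replicate 3, and 2 rose with the replicate block. For the red cell list, between the DMSO groups, 1 fell without Tact DMSO replicate 1. For the stromal list, between the DMSO groups, 2 rose with the replicate block. For the stromal list, with the drug, 1 to 2 rose without 1 library, and 3 rose with the replicate block. For the histone list, with the drug, 2 to 5 rose and 0 fell without 1 library.

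TNFAIP2, CCL22, FN1 and TNC, best known from myeloid cells or fibroblasts, rose with mezigdomide. Monocytes, macrophages or dendritic cells would bring their abundant transcripts. TYROBP, FCER1G, CSF1R and SPI1 together stood at 2.20 ± 0.69 CPM in Tex DMSO and 2.25 ± 1.24 with the drug (highest library 3.67). The sum of 6 genes picked for rising went from 3.04 ± 1.16 to 218 ± 18.6, most of it TNFAIP2 (156) and CCL22 (38.8). The tables argue against such cells for TNFAIP2 and CCL22. S100A9, CD14 and CLEC10A stood at 5.45 CPM or less, too low for this test. For fibroblasts, COL1A1, COL1A2, COL3A1 and DCN together went from 17.2 ± 14.1 to 32.5 ± 27.5 CPM, at most 63.1 in a library against 61.2, which is 10% of the rise of 4 matrix genes, so fibroblasts stay open; DCN was 0 in every library, and COL1A2 differed most between libraries. Within a pair the 4 fibroblast transcripts rose by at most 5.32% of the rise of the matrix genes and the myeloid ones by at most 0.31%. The drug itself stays open, and how it would act was not tested.

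More genes were called in the same direction by the Tex and the drug comparisons (1239) than in opposite directions (531). The Tex DMSO libraries shared by both would push fold changes apart, with a covariance of -0.0936 to -0.0753 in 40 simulations, against an observed 0.136. With spike-in scaling 460 genes were in the same direction (312 higher and 148 lower in both, against 265.6 and 54.2 for independent lists) and 349 in opposite ones (275 and 74, against 329 and 43.8). Their ratio of 1.32 ran from 0.93 to 1.7 when 1 library was left out, lowest without Tex DMSO replicate 2, so scaling stays open. No biological explanation was tested.

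Ribosomal protein genes were lower in Tex DMSO than in Tact DMSO: 76 of 78 fell and 0 rose, and with the drug 40 fell and 0 rose. Their share of reads was 11.9 ± 0.131% in Tact DMSO, 6.69 ± 0.225% in Tex DMSO and 5.44 ± 0.117% in Tex mezigdomide. The median log2 fold change of -0.9 lay outside 1000 draws of genes matched on GC content and length (-0.3 to 0.08), and stayed at -0.9 with that correction. With spike-in scaling the median was -0.45 (-0.58 to -0.36 when 1 library was left out), and ribosomal protein pseudogenes took at most 0.124% of reads in a Tex DMSO library against 0.152 to 0.194% in Tact DMSO, which argues against scaling or shared reads as the whole cause. The difference between the Tex and Tact states stays open, and how it would act was not tested.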
